A study of Homo sapiens with 6 samples.

How the data were processed

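RNA from HT1080 fibrosarcoma cells exposed to SW-113 or SW-138 at 1 µM for 48 h was measured in 6 libraries, 3 per compound, per the labels. Total RNA was extracted from frozen cell pellets and depleted of ribosomal RNA before library preparation, per the labels' protocols. The authors deposited 1 table with a column of expected counts per library. Names in the column headers matched the sample labels, and 0 other sample columns were present. The deposited expected counts are estimates that need not be whole, and 10.56% to 11.56% of the values in a library were not whole. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.5.4, RSEM 1.3.3 and DESeq2 1.42.0 and the genome build GRCh38, with no role or order. The annotation version, filters and strand setting were not given in the sources used here. Reads from overlapping genes on opposite strands therefore may not be separated. RSEM divides reads that map to several places among near-identical genes, so values of such genes are uncertain.

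The table had 60675 gene rows, of which 56558 matched a current gene symbol and 57055 were in GENCODE release 29, the annotation used here for GRCh38 coordinates and gene types. Transcript length and GC content were available for 16784 of the 16905 tested genes (99.3%). Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the compound as group, which left 16905 genes. Library totals ranged from 32771670 to 50871623 counts and TMM factors from 0.9755 to 1.0324. Compounds were compared with edgeR 4.0.16 by the quasi-likelihood test, SW-138 minus SW-113, with no block and Benjamini-Hochberg adjustment over all tested genes at 0.05. Standard errors of log2 fold changes came from limma-voom (limma 3.58.1). The 95% intervals were centred on the edgeR log2 fold changes, with the limma-voom standard errors and degrees of freedom. CPM values used the TMM-scaled library totals. The biological coefficient of variation was 7.56% and the median standard error 0.09 on the log2 scale. R was version 4.3.3.

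Gene lists were 39 lists of 940 entries compiled by hand from textbook knowledge, fixed before the data were examined together with the tests, the rule for named genes and the alternatives to be run. They share genes, such as FTH1 and FTL in the NRF2 and ferroptosis lists and CDKN1A in the p53 list and that of genes commonly raised by class I deacetylase inhibitors. Of the 39, 38 had at least 5 tested members. Camera with a preset correlation of 0.01 tested whether a list's genes ranked apart from other genes, camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the 38 lists by Benjamini-Hochberg. Fry tests whether a list's genes move on balance in one direction and does not compare them with other genes. The estimated correlation came from the same 6 libraries, which leaves that form of camera little power. Genes were named in the text by a rule. HDAC6 and the other genes of HDAC1 to HDAC11 were always named, as were, among others, CDKN1A, TXNIP, DHRS2, CLU, TUBA1B, HSPA1A and SQSTM1. To these came the 10 genes with the largest log2 fold change in each direction among those past the threshold, with no overlap between groups, a mean of at least 1 CPM and a gene symbol, and up to 4 members with the smallest p in each list. Other members past the threshold are named where a list had few of them.

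The fits were tested on simulated data for this comparison, drawn from the means and library totals of the real libraries, with 200 genes changed. That step held 16646 genes. The test recovered 34% of genes with the smallest change (17 of 50) and 52% at 1.5-fold (26 of 49). It recovered 80% at 2-fold (40 of 49) and 84% at 4-fold (42 of 49). Beside these stood 15 false calls, a larger share of all calls than the threshold of the adjustment allows for. A false share above that threshold among the real calls is therefore not excluded. The simulated truth lay in 95.2% of the intervals. In a separate simulated set, where nothing but the p53 list was shifted, by 1.2-fold, that list was called and 0 other lists were. The libraries were simulated with independent genes, so camera's behaviour with correlated genes was not covered.

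Alternatives were other scalings (DESeq2 size factors, upper quartile, total count alone), other filters on low counts, DESeq2 1.42.0, limma-voom and edgeR with robust estimation, a block on replicate number, leaving out each library, leaving out mitochondrial and stable noncoding genes, a test against a fold of 1.5, an adjusted threshold of 0.1 and, chosen after seeing the data, removal of trends with transcript length and GC content, thinning to the smallest library and protein-coding genes alone. Figures were drawn with matplotlib.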

Results

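The series was set up to evaluate the selectivity of inhibitors of KDAC6 (HDAC6), a mainly cytoplasmic lysine deacetylase whose substrates include tubulin and the chaperone HSP90. HT1080 cells, an established human fibrosarcoma line, were exposed to 1 of 2 inhibitors, SW-113 or SW-138, at 1 µM for 48 h. Total RNA was depleted of ribosomal RNA and sequenced. There were 3 libraries per compound and 6 in all, and the labels used here hold no vehicle group, so each compound was compared only with the other. "Higher" and "lower" below mean in SW-138 relative to SW-113. A gene lower in SW-138 could be lowered by SW-138, raised by SW-113, or both, and these libraries do not separate the 3 cases.

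The libraries held 39249722, 50871623 and 41654743 estimated read counts for SW-113 replicates 1, 2 and 3. For SW-138 replicates 1, 2 and 3 the totals were 40527236, 32771670 and 36661221. Between 24925 and 25869 genes had at least 1 count in a library. Pearson correlations of log2 CPM (counts scaled to 1e6 per library) were 0.9877 to 0.9928 within a compound and 0.9858 to 0.9912 between compounds, so the ranges overlapped. SW-138 replicate 2 stood apart on the first principal component (32.2% of the variance), at 39.08 where the other libraries lay from -24.05 to 5.88. It had the lowest correlations within a compound, 0.9877 and 0.9887. The groups accounted for 29.2% of the variance across genes, where 20% is the share that chance gives. No pair of replicates agreed within sampling noise, so each library was counted once. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

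The makeup of the RNA differed between the groups. The signal recognition particle RNA RN7SL1 took 4.11% ± 0.349 of the counts (SD, n = 3) with SW-113 and 2.56% ± 0.380 with SW-138. The stable noncoding RNAs together took 11.8% ± 0.740 and 8.87% ± 1.40, and in both measures every SW-113 library lay above every SW-138 library. Mitochondrial transcripts took 2.12% ± 0.340 and 2.48% ± 0.475, with overlapping libraries.

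At matched dose and time, cells given SW-138 had higher mRNA levels of the class IIa deacetylases HDAC5 and HDAC9, the redox regulator TXNIP, the cytokine IL24 and immediate early transcription factors such as FOS and EGR1 than cells given SW-113. They had lower levels of many targets of p53 and NRF2, of the ferritin subunits FTH1 and FTL, and of cytosolic ribosomal protein mRNAs. HDAC6 mRNA itself was not shown to differ. With few exceptions the differences were small, and the genes past the threshold had a median fold of 1.255.

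Of 60675 genes in the table, 16905 had enough counts to test. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 1153 genes differed, 466 higher and 687 lower in SW-138. Of these, 54 also differed by more than 2-fold, 33 higher and 21 lower. A block on replicate number gave 2363 genes (1093 higher, 1270 lower), and keeping genes at 1 count in 1 library gave 2060 (991 higher, 1069 lower). All 1153 had no overlap between the 3 libraries of each compound, as had 27.88% of all tested genes, where chance gives 10%. The direction of the split depended on scaling: 40.4% of calls were higher with TMM factors, and 71.0% (923 higher, 377 lower) with scaling by total count alone. Leaving out single libraries gave 530, 458 and 303 genes without SW-113 replicates 1, 2 and 3, and 509, 1616 and 605 genes without SW-138 replicates 1, 2 and 3.

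**Figure D1:**
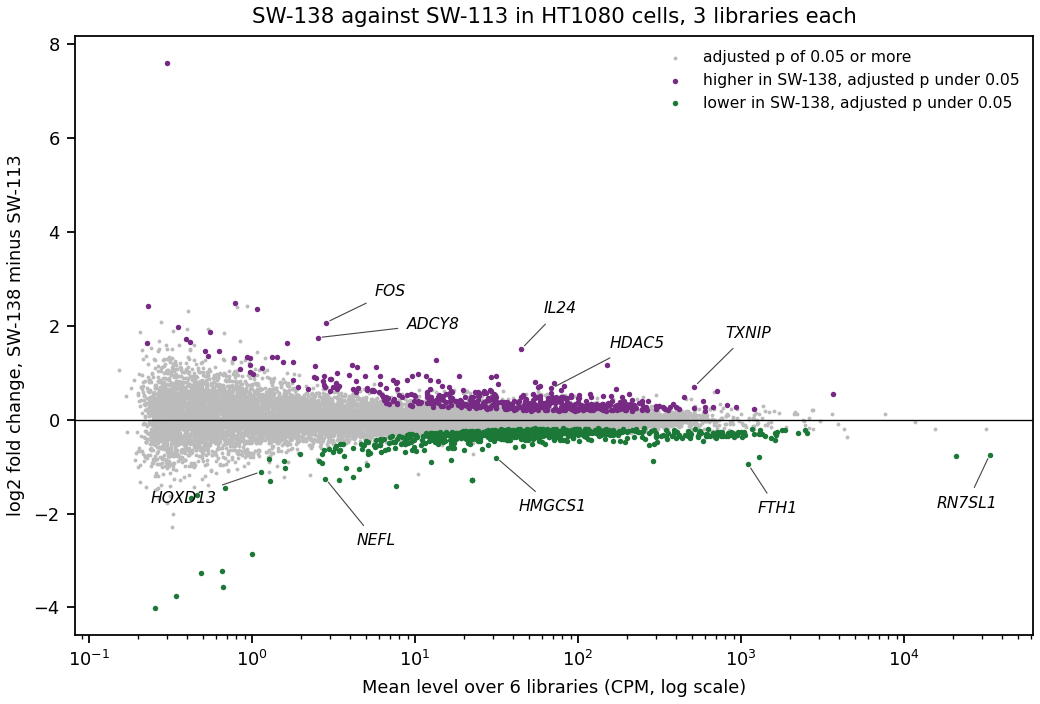
Log2 fold change of each tested gene, SW-138 minus SW-113, against its mean level over 6 libraries in CPM on a log axis, with genes at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg) in colour. Of 1153 coloured genes 466 lie above 0 and 687 below, and the fitted values of genes near 0 CPM in one group depend on the prior count.

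Among deacetylase genes, HDAC5 and HDAC9 were the members that differed. HDAC6 (ENSG00000094631, GRCh38 chromosome X, 48801377 to 48824982) was at 13.5 ± 1.04 CPM (SD, n = 3) with SW-113 and 14.7 ± 0.568 CPM with SW-138. Its log2 fold change was 0.13 ± 0.08 (SE), with a 95% interval of -0.05 to 0.31 and an adjusted p of 0.374 (edgeR, Benjamini-Hochberg). HDAC5 (ENSG00000108840, chromosome 17, 44076746 to 44123702) was 1.59-fold higher, at 84.3 ± 2.79 CPM against 53.03 ± 2.92 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.000445). HDAC9 (ENSG00000048052, chromosome 7, 18086949 to 19002416) was 1.40-fold higher, at 80.7 ± 4.70 CPM against 57.8 ± 4.28 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.00388). The other members of HDAC1 to HDAC11 did not pass, with log2 fold changes from -0.20 in HDAC10 to 0.06 in HDAC7. The intervals of the class I genes HDAC1, HDAC2 and HDAC3 ran from -0.17 to 0.04, from -0.08 to 0.16 and from -0.19 to 0.06. In the list of 17 tested deacetylase genes 2 were higher, 0 were lower and 15 did not pass, with 2 passing when adjusted over the list alone. In the list of subunits of class I deacetylase corepressor complexes 0 of 27 were higher and 2 were lower, GPS2 (-0.29 ± 0.06, SE) and MTA1 (-0.19 ± 0.05), again with 2 adjusted over the list alone. The calls named next were lost without the libraries given, with the log2 fold change over the 6 fits that left out a library in brackets. GPS2 (-0.32 to -0.27) did not pass without SW-113 replicate 2 or 3. MTA1 (-0.20 to -0.16) did not pass in any of the 6 fits.

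Genes commonly raised by inhibitors of class I deacetylases did not move together. Of 24 tested, 4 were higher, 1 was lower and 19 did not pass, with 7 passing when adjusted over the list alone (4 higher, 3 lower). TXNIP, a thioredoxin-binding protein, was at 639 ± 16.97 CPM (SD, n = 3) with SW-138 and 393 ± 31.8 CPM with SW-113, a log2 fold change of 0.70 ± 0.06 (SE, edgeR, Benjamini-Hochberg adjusted p = 0.00086). GADD45B was higher by 0.52 ± 0.10. CDKN1A, which encodes the cell cycle inhibitor p21, went the other way at -0.42 ± 0.06 (edgeR, Benjamini-Hochberg adjusted p = 0.00602). DHRS2 and CLU did not pass, with log2 fold changes of 0.13 ± 0.05 and -0.01 ± 0.12. Of the 20 tested genes commonly lowered by such inhibitors, 1 was higher, 0 were lower and 19 did not pass, with 3 higher when adjusted over the list alone. The one that passed was CCND1, which encodes cyclin D1, at 0.40 ± 0.05. As a group these 20 lay higher than other genes (camera adjusted p = 0.0247), with an adjusted p = 0.677 with an estimated correlation, 0.21 without SW-113 replicate 2 and 0.0592 without SW-138 replicate 3. Neuronal genes repressed by REST had 2 of 15 higher, BDNF (0.57 ± 0.06) and STMN3 (0.46 ± 0.09), and 1 lower, the neurofilament gene NEFL (-1.26 ± 0.17), with 6 adjusted over the list alone (5 higher, 1 lower). The replicate block called 6 REST genes higher and 1 lower, and scaling by total count alone 4 higher and 1 lower. In the list of commonly lowered genes each of these called 3 higher. The group test of the REST list gave a camera adjusted p of 0.0095, and an adjusted p = 0.391 with an estimated correlation. With genes kept at 1 count in 1 library, 24 REST genes were tested and the list did not pass (adjusted p = 0.13, median 0.17 against 0.29). Certain of these calls were lost when a library was left out. GADD45B (0.43 to 0.58) did not pass without SW-113 replicate 2. STMN3 (0.38 to 0.56) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1.

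Genes tied to KDAC6 function showed small differences in both directions. TUBA1B, a tubulin gene, was at -0.09 ± 0.06 (SE) and the autophagy receptor gene SQSTM1 at -0.29 ± 0.08, and neither passed. HSPA1A, an inducible HSP70 gene, was at 20.6 ± 2.65 CPM (SD, n = 3) with SW-138 against 28.3 ± 0.934 CPM with SW-113, a log2 fold change of -0.45 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.0131). Among 29 tubulin genes and tubulin modifiers 2 were higher, TUBE1 among them, 3 were lower, TUBB2A, TUBA1A and TBCA, and 24 did not pass, with 8 passing when adjusted over the list alone (2 higher, 6 lower). TUBB2A had the largest of these differences, at -0.50 ± 0.09. The tubulin list lay lower as a group (camera adjusted p = 0.0095), with an adjusted p = 0.677 with an estimated correlation, 0.0621 without SW-113 replicate 3 and 0.0877 with genes kept at a mean of 5 CPM. Of 23 KDAC6 partners and aggresome genes, PPP1R12A was higher, the dynein light chain gene DYNLL1 was lower (-0.39 ± 0.05) and 21 did not pass, with 4 adjusted over the list alone (1 higher, 3 lower). The replicate block called 1 higher and 4 lower, and keeping genes at 1 count in 1 library 1 higher and 3 lower. In the tubulin list the replicate block called 2 higher and 7 lower. The heat shock list had 0 of 20 higher and 6 lower, among them HSPE1 (-0.38 ± 0.06), HSPA8 (-0.32 ± 0.05) and DNAJB1 (-0.31 ± 0.05), with 8 lower adjusted over the list alone. Its camera adjusted p was 4.64e-06, and it had an adjusted p = 0.605 with an estimated correlation. One of 32 cilium genes was lower, IFT20, and 1 of 32 autophagy and lysosome genes, GABARAP, with 1 in each adjusted over the list alone. Scaling by total count alone left the cilium list with 0 lower and 1 higher and the autophagy list with 1 of each, and the replicate block called 1 higher and 2 lower, and 1 higher and 3 lower. Not all of the calls held when a library was left out. HSPA1A (-0.56 to -0.39) did not pass without SW-113 replicate 2 or 3 or SW-138 replicate 1. TUBE1 (0.25 to 0.30) did not pass without SW-113 replicate 1 or 3. TUBB2A (-0.59 to -0.42), TUBA1A (-0.36 to -0.29), HSPE1 (-0.44 to -0.33), HSPA8 (-0.35 to -0.28) and DNAJB1 (-0.34 to -0.26) did not pass without SW-113 replicate 3. TBCA (-0.26 to -0.22) did not pass without SW-113 replicate 1 or 3 or SW-138 replicate 1. PPP1R12A (0.19 to 0.23) and IFT20 (-0.31 to -0.23) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1 or 3. GABARAP (-0.39 to -0.26) did not pass without SW-113 replicate 2 or 3 or SW-138 replicate 1 or 3.

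**Figure D2:**
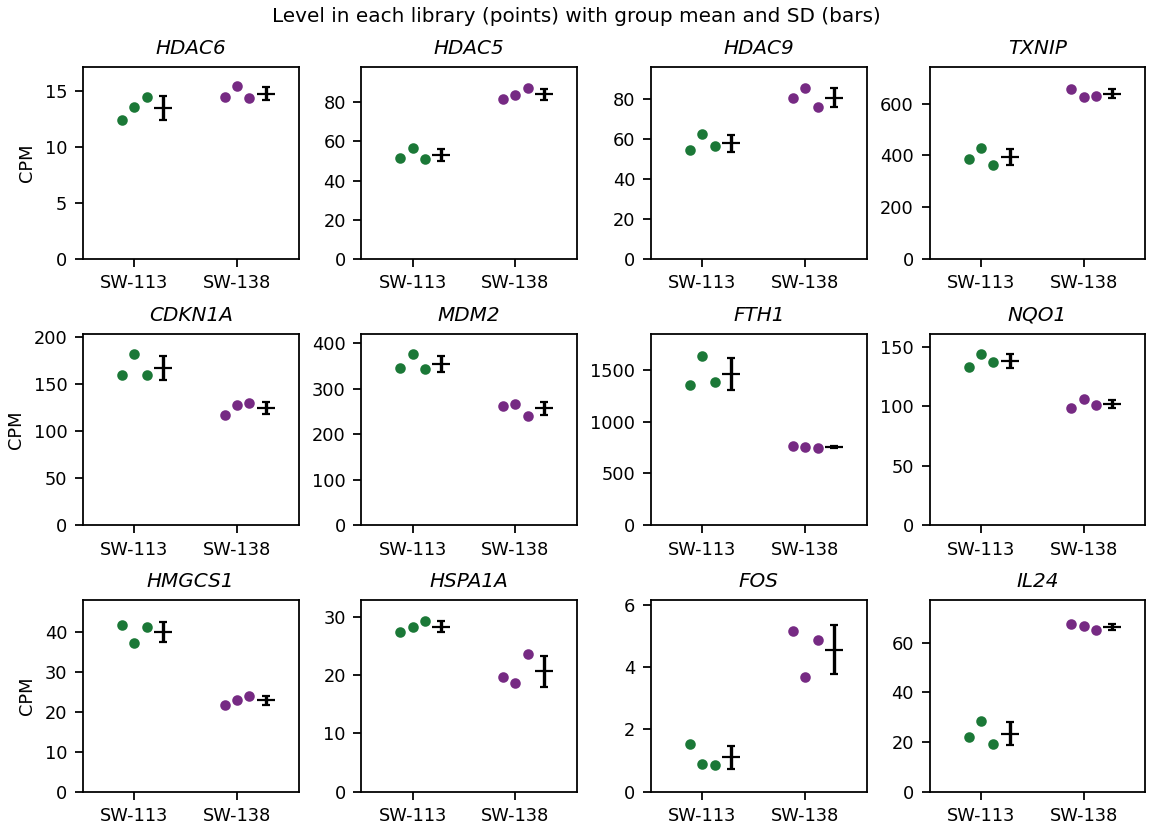
Level of 12 genes in each library, in CPM on axes that start at 0, with points for the 3 libraries of each compound and bars for the mean and SD. HDAC6 lies at 13.5 and 14.7 CPM in the groups, while HDAC5, HDAC9, TXNIP, FOS and IL24 lie higher with SW-138 and CDKN1A, MDM2, FTH1, NQO1, HMGCS1 and HSPA1A lie lower, each with no overlap between groups.

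Many targets of p53 and of NRF2 were lower in SW-138. Of 25 p53 targets tested, 15 were lower, 1 was higher and 9 did not pass, with 18 passing when adjusted over the list alone (1 higher, 17 lower). The p53 ligase gene MDM2 was at 257 CPM with SW-138 and 355 CPM with SW-113 (-0.47 ± 0.06, SE). FDXR, which serves mitochondrial electron transfer, was at -0.63 ± 0.09, the proapoptotic gene BAX at -0.45 ± 0.06 and TP53INP1 at -0.55 ± 0.08. The member that was higher was SESN2, which also belongs to the ATF4 list. The p53 list had a camera adjusted p of 4.42e-10, and an adjusted p = 0.391 with an estimated correlation. Of 23 NRF2 targets, 13 were lower, 0 were higher and 10 did not pass, with 15 lower adjusted over the list alone. FTH1 (ENSG00000167996, chromosome 11, 61959718 to 61967660), the ferritin heavy chain gene, was 1.93-fold lower, at 754 ± 6.75 CPM against 1460 ± 153 CPM (SD, n = 3; edgeR, Benjamini-Hochberg adjusted p = 0.000445). FTL, the ferritin light chain gene, was at -0.80 ± 0.08. The quinone reductase gene NQO1 was at -0.44 ± 0.05. The NRF2 list had a camera adjusted p of 1.08e-13, and an adjusted p = 0.373 with an estimated correlation. Not all of these calls held without 1 library. SESN2 (0.20 to 0.28) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1 or 3.

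Ferroptosis regulators overlapped with the NRF2 list through FTH1, FTL and HMOX1. Of 18 tested, 5 were lower, 1 was higher and 12 did not pass, with 7 adjusted over the list alone (1 higher, 6 lower). The transferrin receptor gene TFRC was at -0.53 ± 0.06 (SE) and GPX4, whose enzyme reduces lipid peroxides, at -0.45 ± 0.07. The camera adjusted p was 0.00682, with an adjusted p = 0.373 with an estimated correlation. Of 6 metallothionein and zinc response genes, MT1X and MT2A were lower, with 2 adjusted over the list alone, and with scaling by total count alone 0 were lower. Of 7 targets of the aryl hydrocarbon receptor, SERPINB2 was higher (0.85 ± 0.11) and NQO1 lower, with 2 adjusted over the list alone. Of 24 cholesterol synthesis genes, 6 were lower, 0 were higher and 18 did not pass, with 7 lower adjusted over the list alone, 9 with the replicate block and 4 with scaling by total count alone. HMGCS1, which makes HMG-CoA, was at 22.9 CPM with SW-138 and 40.03 CPM with SW-113 (-0.81 ± 0.07), and INSIG1, IDI1 and STARD4 were at -0.36 ± 0.06, -0.35 ± 0.06 and -0.33 ± 0.06. The cholesterol list had a camera adjusted p of 2.48e-05, and an adjusted p = 0.649 with an estimated correlation. Among 19 genes of fatty acid and lipid synthesis edgeR called 0, with 2 at an unadjusted p under 0.05, 0 called by DESeq2 or limma-voom and 1 called higher with scaling by total count alone. Several of these calls were lost in fits that left out a library. MT1X (-0.41 to -0.28) did not pass without SW-113 replicate 2 or 3 or SW-138 replicate 1 or 3. MT2A (-0.31 to -0.18) did not pass without SW-113 replicate 1 or 3 or SW-138 replicate 1 or 3. INSIG1 (-0.41 to -0.31), IDI1 (-0.38 to -0.30) and STARD4 (-0.37 to -0.29) did not pass without SW-113 replicate 3.

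Ribosomal protein mRNAs were lower almost throughout. Of 51 cytosolic ribosomal protein genes tested, 43 were lower, 0 were higher and 8 did not pass, with 50 lower adjusted over the list alone. Their mean log2 fold change was -0.30, and RPLP2 was at -0.44 ± 0.05 (SE), RPS23 at -0.36 ± 0.04, RPS12 at -0.39 ± 0.05 and RPS27 at -0.41 ± 0.05. The share of counts in ribosomal protein genes was 4.18% ± 0.0930 (SD, n = 3) with SW-138 and 4.84% ± 0.203 with SW-113. The list had a camera adjusted p of 1.66e-40, and an adjusted p = 0.373 with an estimated correlation. Nuclear genes of the respiratory chain had 8 of 33 lower and 0 higher, among them COX5B (-0.36 ± 0.06) and UQCRB (-0.30 ± 0.05), with 19 lower adjusted over the list alone and 18 lower with the replicate block. Their camera adjusted p was 1.5e-10, with an adjusted p = 0.391 with an estimated correlation. Of 13 mRNAs from the mitochondrial genome edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. With genes kept at 1 count in 1 library edgeR called 5 of them higher and 1 lower, with the replicate block 2 higher and 1 lower, and without SW-138 replicate 2 it called 1 higher. The ribosomal protein and respiratory chain lists were lower alongside the shift in RNA makeup described above, and short transcripts were lower in general. The 10% of protein-coding genes with the shortest transcripts, from 207 to 1639 bases, had 11 genes higher and 220 lower, and the 10% with the longest had 76 higher and 16 lower. Of 9 stable noncoding RNAs, RN7SL1 (-0.74 ± 0.10) and RN7SL2 (-0.77 ± 0.11) were lower and 0 were higher, with 5 adjusted over the list alone and with the replicate block (1 higher, 4 lower in both), and their reads can be shared among near-identical copies. That list had a camera adjusted p of 0.0095, and an adjusted p = 0.677 with an estimated correlation. With trends in transcript length and GC content removed it did not pass (adjusted p = 0.342), and its median went from -0.25 to -0.14. The nuclear RNA MALAT1 was the member of 8 nuclear and long noncoding transcripts that passed, at 0.55 ± 0.06, with 1 adjusted over the list alone, and the replicate block called 4 higher and 1 lower. Not every call held when a library was left out. UQCRB (-0.33 to -0.27) did not pass without SW-113 replicate 3.

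Several immediate early genes were higher in SW-138. Of 22 tested, 9 were higher, 1 was lower and 12 did not pass, with 14 adjusted over the list alone (13 higher, 1 lower) and 14 higher and 1 lower with the replicate block. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) was 4.19-fold higher, at 4.56 ± 0.787 CPM against 1.1 ± 0.375 CPM (SD, n = 3; edgeR, Benjamini-Hochberg adjusted p = 0.00185). FOSB was higher by 2.48 ± 0.30 (SE), a value that rests on 0.237 CPM with SW-113 and 1.34 CPM with SW-138. EGR1 was higher by 0.98 ± 0.12, from 7.03 CPM with SW-113. DUSP4, a phosphatase gene that acts on MAP kinases, was lower (-0.37 ± 0.04). The list had a camera adjusted p of 9.82e-07, and an adjusted p = 0.383 with an estimated correlation. The ATF4 integrated stress response list had 4 of 27 higher and 0 lower, ATF3 (0.44 ± 0.08), PCK2 (0.28 ± 0.06), DDIT3 (0.35 ± 0.09) and SESN2 (0.23 ± 0.06), with 9 higher adjusted over the list alone, 9 with scaling by total count alone and 11 with the replicate block. Its camera adjusted p was 0.000562, with an adjusted p = 0.391 with an estimated correlation. In the unfolded protein response list 1 of 20 was lower, SEC61B, with 0 adjusted over the list alone, and with scaling by total count alone 2 were higher and 0 lower. Among NF-kB and inflammatory genes IL11 (0.55 ± 0.08), TRAF1 (0.55 ± 0.10) and IL6 (0.69 ± 0.14) were higher and NFKBIA (-0.36 ± 0.07) was lower, of 21 tested, with 9 adjusted over the list alone (6 higher, 3 lower). In that list the replicate block and keeping genes at 1 count in 1 library each called 6 higher and 1 lower, and scaling by total count alone 5 higher and 1 lower. Among 28 interferon-stimulated genes edgeR called 0, with 10 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Scaling by total count alone called 3 of them higher, and 1 was called lower with the replicate block, with genes kept at 1 count in 1 library, and without SW-138 replicate 2. Some of these calls were lost when a library was left out, which also lowers the power of the test. PCK2 (0.24 to 0.31) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 3. DDIT3 (0.28 to 0.47) did not pass without SW-113 replicate 1 or 3 or SW-138 replicate 1 or 3. SESN2 (0.20 to 0.28) and SEC61B (-0.36 to -0.23) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1 or 3. TRAF1 (0.48 to 0.61) did not pass without SW-113 replicate 3. IL6 (0.63 to 0.77) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1. NFKBIA (-0.40 to -0.33) did not pass without SW-113 replicate 2 or 3 or SW-138 replicate 1.

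**Figure D3:**
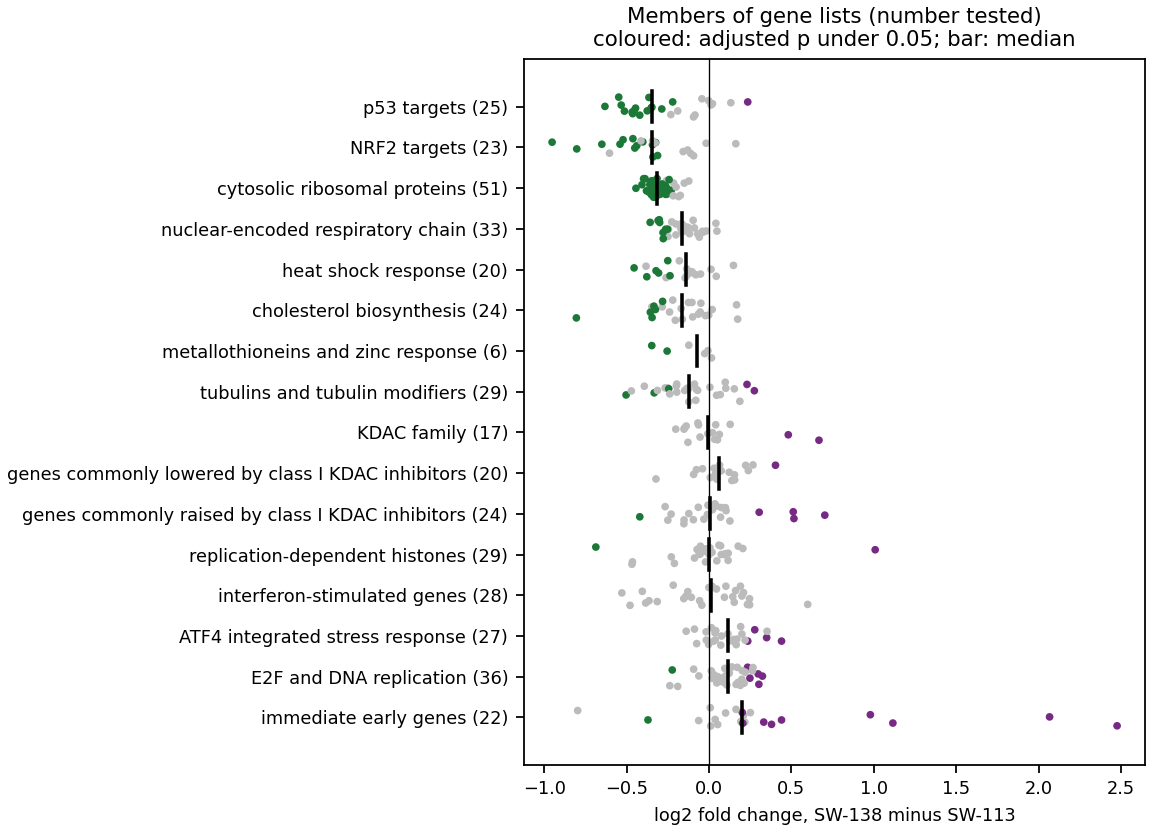
Log2 fold change, SW-138 minus SW-113, of each tested member of 16 gene lists, with the number tested in brackets, members at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg) in colour and a bar at the median. All 51 ribosomal protein genes lie below 0, 21 of 25 p53 targets and 22 of 23 NRF2 targets do, and 19 of 22 immediate early genes lie above 0.

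Genes of growth and of cell identity held calls in both directions. Of 36 E2F and DNA replication genes 5 were higher, among them MCM6 (0.23 ± 0.05, SE), MCM3 (0.30 ± 0.06) and MCM2 (0.25 ± 0.05), and 1 was lower, where scaling by total count alone called 13 higher and 0 lower and the replicate block 12 higher and 1 lower. Adjusted over the list alone, 14 passed (13 higher, 1 lower), and the camera adjusted p was 3.28e-05, with an adjusted p = 0.677 with an estimated correlation. Of 32 genes of G2 and mitosis, ASPM was higher (0.26 ± 0.07), with 0 adjusted over the list alone. The replicate block and keeping genes at 1 count in 1 library each called 8 of these higher, and scaling by total count alone 3. As a group they lay higher (camera adjusted p = 0.000639), with an adjusted p = 0.844 with an estimated correlation and 0.351 without SW-113 replicate 2. Replication-dependent histones had 1 of 29 higher, H4C9, and 1 lower, H4C1, with 2 adjusted over the list alone, and these genes share reads with near-identical copies. In glycolysis 2 of 20 were lower, PFKFB4 and ALDOA, with 4 adjusted over the list alone (1 higher, 3 lower), and scaling by total count alone called 1 higher and 0 lower and the replicate block 1 higher and 5 lower. The glycolysis list had a camera adjusted p of 0.00521, an adjusted p = 0.677 with an estimated correlation, and 0.0548 with scaling by total count alone, where its median went from -0.10 to -0.04. In the hypoxia list LOX and STC1 were higher, and BNIP3 and EGLN1 lower, of 20 tested, with 4 adjusted over the list alone. Of 29 extracellular matrix and TGF-beta response genes, 3 were higher, among them MMP1 (0.48 ± 0.07) and LOX, and TGFBI was lower, with 6 adjusted over the list alone (5 higher, 1 lower). In that list scaling by total count alone called 5 higher and 0 lower, and the replicate block 11 higher and 3 lower. Among 23 YAP and SRF targets, 3 were higher, among them ANKRD1 (0.47 ± 0.06), and MYL9 (-0.51 ± 0.07), ACTA2 (-0.60 ± 0.09) and ACTG1 (-0.28 ± 0.04) were lower, with 12 adjusted over the list alone (8 higher, 4 lower). Scaling by total count alone called 8 higher and 3 lower, and the replicate block 10 higher and 5 lower. The mesenchymal transcription factor genes SNAI2, TWIST1 and TWIST2 were lower, of 12 mesenchymal genes tested, with 5 adjusted over the list alone (2 higher, 3 lower). Scaling by total count alone called 2 higher and 2 lower, and the replicate block 2 higher and 3 lower. Of markers of other cell types, edgeR called 0 of 6 epithelial and 0 of 7 endothelial genes, with 0 in each at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Of the endothelial genes 2 were called higher with the replicate block, with genes kept at 1 count in 1 library, and without SW-138 replicate 2. Of 7 immune cell markers LCP1 was lower, with 1 adjusted over the list alone, and scaling by total count alone called 0. Of the 12 erythroid markers 1 had enough counts, so that list was not tested. Many of the calls in these lists were lost in fits that left out a library. MCM6 (0.21 to 0.26) and MCM2 (0.22 to 0.29) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 3. MCM3 (0.25 to 0.34), ALDOA (-0.25 to -0.17), STC1 (0.36 to 0.60), EGLN1 (-0.24 to -0.21), TWIST2 (-0.36 to -0.26) and LCP1 (-0.32 to -0.20) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1 or 3. ASPM (0.20 to 0.34) did not pass without SW-113 replicate 1 or 2 or SW-138 replicate 1, 2 or 3. H4C9 (0.92 to 1.19) and TGFBI (-0.25 to -0.23) did not pass in any of the 6 fits. H4C1 (-0.79 to -0.64), ACTG1 (-0.30 to -0.26), SNAI2 (-0.39 to -0.32) and TWIST1 (-0.44 to -0.39) did not pass without SW-113 replicate 3. PFKFB4 (-0.35 to -0.25) did not pass without SW-113 replicate 1 or 3 or SW-138 replicate 1 or 3. LOX (0.29 to 0.41) did not pass without SW-113 replicate 2 or 3 or SW-138 replicate 1.

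Among all genes past the threshold with a current symbol, a mean of at least 1 CPM and no overlap between groups, the 10 with the largest increases in SW-138 over SW-113 were SLC9A3P2, FOS, ADCY8, TMBIM4, IL24, KLB, H4C15, SCARNA10, PRSS53 and NR4A3. IL24 (ENSG00000162892, chromosome 1, 206897443 to 206904139) was at 66.3 ± 1.18 CPM (SD, n = 3) against 23.3 ± 4.63 CPM, a log2 fold change of 1.51 ± 0.11 (SE). ADCY8, an adenylyl cyclase gene, was higher by 1.75 ± 0.19 and KLB, a coreceptor for fibroblast growth factors, by 1.34 ± 0.21. The TMBIM4 value of 1.64 belongs to a second identifier absent from the annotation used here, and the main TMBIM4 gene was at -0.28 ± 0.08, short of the threshold. H4C15 (1.28 ± 0.15) shares its sequence with near-identical copies, of which H4C14 was at 0.10 ± 0.10. The 10 with the largest decreases were MT-RNR2, SULT1A3, NEFL, CT45A9, HOXD13, MT-RNR1, RN7SL151P, RPS28P7, FTH1 and FLRT3. NEFL was at 1.66 ± 0.229 CPM with SW-138 against 3.98 ± 0.422 CPM with SW-113. MT-RNR2 (-1.41 ± 0.32) and MT-RNR1 (-1.05 ± 0.27) are ribosomal RNAs, measured here after depletion of ribosomal RNA. SULT1A3 (-1.32 ± 0.34), CT45A9, RN7SL151P and RPS28P7 have close copies that can share reads, and SULT1A4 was at 0.18 ± 0.29. SLC9A3P2 is a pseudogene and its value of 2.37 ± 0.35 rests on 0.348 and 1.79 CPM. A second SCARNA10 identifier was at 0.03 ± 0.10. Many of these calls were lost when a library was left out. SCARNA10 (1.07 to 1.56) did not pass without SW-113 replicate 1 or 3 or SW-138 replicate 1 or 3. PRSS53 (1.08 to 1.54), SULT1A3 (-1.57 to -1.05) and CT45A9 (-1.62 to -0.94) did not pass without SW-113 replicate 2 or 3 or SW-138 replicate 1 or 3. MT-RNR2 (-1.67 to -1.06) did not pass without SW-138 replicate 1. HOXD13 (-1.36 to -0.94) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 3. MT-RNR1 (-1.28 to -0.73) did not pass without SW-113 replicate 1 or 2 or SW-138 replicate 1 or 3. RPS28P7 (-1.15 to -0.83) did not pass without SW-113 replicate 1, 2 or 3 or SW-138 replicate 1 or 3. FLRT3 (-1.05 to -0.84) did not pass without SW-113 replicate 3.

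How far the compounds can differ was bounded gene by gene. The 95% interval of the difference lay inside a 1.5-fold change in either direction for 11527 genes, 68.19% of those tested, and inside a 2-fold change for 14247 genes (84.28%). Of the former, 818 were also past the threshold, so their difference was detected and small. For 70 genes the interval lay wholly beyond 1.5-fold. A stricter edgeR test against a fold of 1.5 with Benjamini-Hochberg adjustment called 5 genes. FOS, FOSB, ADCY8 and IL24 were higher, of which FOSB had a mean of 0.790 CPM over the 6 libraries. RP11-196G11.1, a gene known by a clone name and named here after its value was seen, was lower. Of 38 lists tested, 16 passed camera with its preset correlation, 6 higher and 10 lower. Fry passed 7, those of ribosomal proteins, respiratory chain, NRF2, p53, immediate early, ferroptosis and REST genes. With an estimated correlation 0 passed camera, and 4 had an unadjusted p under 0.05. In that test the ribosomal protein list, with all 51 members below 0, reached an unadjusted camera p of 0.0295. A list that failed it is thus not shown to be unmoved. Of the 16, 8 had a lower camera p in a split of the libraries that mixes the compounds, those of G2 and mitosis, E2F, cholesterol synthesis, ATF4, glycolysis, tubulin, stable noncoding RNAs and genes commonly lowered by class I deacetylase inhibitors. Some lists that did not pass were called by camera under another setting. Without SW-113 replicate 1 these were KDAC6 partners (adjusted p = 0.0235), metallothioneins (0.0491) and extracellular matrix genes (0.00639). Leaving out SW-113 replicate 2 added metallothioneins (0.0435) and histones, which lay lower there (0.0302). Extracellular matrix genes (0.0434) and mitochondrial genome mRNAs (0.0189) came in without SW-113 replicate 3. Leaving out SW-138 replicate 1 added histones, but here as higher (0.0476). Leaving out SW-138 replicate 2 added the unfolded protein response (0.00959), extracellular matrix genes (2.86e-06), YAP and SRF targets (0.00959) and mitochondrial genome mRNAs (0.000987). The replicate block added extracellular matrix genes (0.00544), YAP and SRF targets (0.0127) and mitochondrial genome mRNAs (0.0107). Removing the length and GC trends added KDAC6 partners (0.00911), histones, again as higher (0.00227), and mitochondrial genome mRNAs (0.0285). Keeping genes at 1 count in 1 library added KDAC6 partners (0.018) and extracellular matrix genes (0.0485), and keeping genes at 1 CPM in 3 libraries added the latter (0.0493).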

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

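The correction for transcript length and GC content, thinning to the smallest total and the restriction to protein-coding genes were chosen after seeing the data. All other alternatives were planned. Every one of the 1153 calls kept its sign in each alternative in which its gene was tested. None of these genes overlapped between groups, so leaving out a library could hardly reverse a sign, and this is a weak check. The number of genes past the threshold depended on the filter, the block, the threshold and the libraries used. With no filter beyond 1 count in 1 library there were 2060 genes (991 higher, 1069 lower), where 31501 genes were tested. At an adjusted p under 0.1 there were 2012 (832 higher, 1180 lower). A test against a fold of 1.5 left 5 (4 higher, 1 lower). Scaling by total count alone gave 923 higher and 377 lower, since it shifted the median of all genes by 0.06. With the replicate block 2363 genes passed (1093 higher, 1270 lower), and all 1153 calls were among them. Same-numbered libraries had deviation correlations of 0.049, 0.206 and 0.051, not all above 0.1, so the samples were taken to share only a number. SW-113 replicate 1 correlated no better with SW-138 replicate 1 (0.049) than with SW-138 replicate 3 (0.052). SW-113 replicate 3 did so less with SW-138 replicate 3 (0.051) than with SW-138 replicate 1 (0.090). SW-113 replicate 2, however, was at 0.206 with SW-138 replicate 2 against -0.142 and -0.104 with SW-138 replicates 1 and 3. A shared effect of replicate number thus stays open. The blocked count had been seen when the choice of no block was settled, by a rule fixed beforehand.

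Without 1 library the count ran from 303, without SW-113 replicate 3, to 1616, without SW-138 replicate 2, with 149 to 803 higher and 154 to 813 lower. The other 4 gave 530 and 458 without SW-113 replicates 1 and 2, and 509 and 605 without SW-138 replicates 1 and 3. Fewer libraries lower the power of the test, and the rise without SW-138 replicate 2 goes the other way; that library stood apart from the other 5 on the first principal component, and the cause was not tested. Of 106 named genes past the threshold, 47 passed in all 6 of these fits and 3 (MTA1, H4C9 and TGFBI) in none. The number of lists past the threshold was 16 and ran from 15 to 20 without 1 library, but was 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 7 with fry. Replication-dependent histones had a median of -0.001 and did not pass, but other settings called them in both directions. They were higher with the length and GC correction, at 0.136 (camera adjusted p = 0.00227), and without SW-138 replicate 1, at 0.079 (adjusted p = 0.0476). Without SW-113 replicate 2 they were lower (camera adjusted p = 0.0302). Over the fits without 1 library the median ran from -0.085 to 0.085, and the cause was not tested. The number of genes with an interval inside 1.5-fold ran from 10941 to 11440 without 1 library. The length and GC correction kept 943 of the 1153 calls among 1249. At this depth and number of libraries, the smallest simulated differences were recovered in 34% of genes, so genes that did not pass are not shown to be alike.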

Other observations

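The tests of length and GC trends, of single libraries, of scaling, of harvest, of CREB targets and of other splits of the samples were chosen after the results were seen. Those of matched lists, of ARRDC4 and of chromosomes were written before. The readings of the ARRDC4 and CREB tests were changed after their values were seen. That of ARRDC4 went from undecided to against, and that of CREB from against to undecided.

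Medians of other gene classes lay on both sides of 0, and their differences were not tested. Genes annotated as sense intronic had a median log2 fold change of 0.25 over 139 genes, antisense genes 0.09 over 973 and long intergenic noncoding genes 0.08 over 859, while protein-coding genes lay at -0.004 over 13309. Going the other way, the class of miscellaneous RNAs had a median of -0.73 over 15 genes with 5 lower, small nucleolar RNAs -0.34 over 11, and mitochondrial ribosomal RNAs -1.23 over 2. In the first 3 of these classes few genes passed edgeR's test, 3, 16 and 18 in turn.

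Ribosomal protein mRNAs were lower in SW-138, and short transcripts in general were lower too, with a Spearman correlation across 13300 protein-coding genes of 0.27 between length and log2 fold change. Removing each library's trend with length and GC content left a correlation of 0.08 and a list median of -0.27, which argues against that trend as the whole cause, though the removal was incomplete. Random lists matched in coarse bins of length and expression had medians from -0.13 up to -0.02 in their central 95%, and the list lay below these. Length was that of a gene's longest transcript. Within a bin the members can still be shorter or more abundant than their matches. A loss of the shortest and most abundant transcripts is therefore not excluded. Under the 3 other scalings the median nearest to 0 was -0.25. DESeq2 size factors, upper quartile and total count shifted the median of all genes by 0.006, 0.008 and 0.064, too little to bring the list near 0. The list thus did not hang on the choice among these scalings, and a larger error of scaling was not tested. A difference in RNA yield or library preparation between the groups, which would also bear on the lower share of RN7SL1, and an effect of the compounds both stay open, and no label gives a batch.

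Targets of p53 and of NRF2 were lower in SW-138 with medians of -0.35 and -0.34. With the length and GC trend removed the medians were -0.34 and -0.37, which argues against that trend. The median nearest to 0 over the fits without 1 library was -0.28 for p53 targets and -0.34 for NRF2 targets, so no single library carries either pattern. A hypothesis is that the compounds differ in their effect on p53 and NRF2 activity, through a higher level with SW-113 or a lower one with SW-138, which only a vehicle group could separate. It was not tested. An estimated correlation ends both list calls, while both passed fry (fry adjusted p = 0.0333 for p53 and 0.0172 for NRF2 targets). Fry does not compare a list with other genes.

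Immediate early mRNAs were higher in SW-138. The median was 0.22 with the length and GC trend removed and 0.175 in the fit without 1 library that lay nearest to 0, which argues against both as the cause. The lowest SW-138 library lay 0.30 above the highest SW-113 library in the mean log2 deviation of the list, but handling at harvest raises these genes, and if each group was harvested together the compounds and the harvest cannot be told apart. Higher activity of CREB was a candidate explanation. Of 15 CREB targets outside the fixed lists 2 passed higher and 0 lower, PER1 and NR4A3. At least 3 had been required, so the prediction was not met, and NR4A3 had been seen before the list was written. The result was first read as against CREB and then, with the values seen, as undecided, so it gives CREB no backing.

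Higher activity of the glucose sensor MondoA was a candidate explanation for TXNIP. Another of its targets, ARRDC4, was at 0.033 ± 0.086 (SE, edgeR, Benjamini-Hochberg adjusted p = 0.853), with an interval far below the value of TXNIP. The prediction that ARRDC4 would be higher was not met, which counts against MondoA only as far as a single target can show. A change of copy number of a chromosome was a candidate cause of the calls, but the largest median of a chromosome was 0.043 in size, which counts against it.

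The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1153 genes and the highest other 1. It left 5378 genes with an interval not inside 1.5-fold, and the highest other left 5283. For camera with a preset correlation the real split gave 16 lists and the highest other 15, so lists passed in groupings that mix the compounds, and the count of lists is not by itself a sign of the compounds. In 8 of the 38 lists tested the real split had the lowest camera p of the 10, where chance gives 1 list in 10. They were those of ribosomal proteins, respiratory chain, NRF2, p53, heat shock, immediate early, ferroptosis and REST genes. In the other 8 lists past the threshold a split that mixes the compounds had a lower camera p, those of G2 and mitosis (0.000168 against 1.7e-18), E2F (6.9e-06 against 2.7e-11), cholesterol synthesis (4.58e-06 against 6.39e-11), ATF4, glycolysis, tubulin, stable noncoding RNAs and genes commonly lowered by class I deacetylase inhibitors. In 4 of these 8 the real split still had the largest median in size, ATF4 (0.115 against 0.065), tubulin (0.123 against 0.075), cholesterol synthesis (0.166 against 0.149) and glycolysis (0.102 against 0.083), so the 2 measures differ and the tie of these 4 to the compounds stays open.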
